A study of Macaca mulatta with 6 samples.

How the data were processed

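HMST-Seq profiles CCGG sites by sequencing tags next to sites cut in separate digests of DNA. Per the labels' protocols, DNA was extracted with a QIAamp kit and the libraries were sequenced as single-end 50 bp reads on a HiSeq2000. The 6 libraries are an HpaII, a BGT_MspI and an MspI digest of each of 2 cell types, with 1 library each. Nothing was replicated, so intervals and permutation tests describe these tables and not the cell types.

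The authors deposited 1 table per cell type, tied to its 3 libraries by the labels. Each has 10 columns and no header. The columns were read as chromosome, position and 2 pairwise comparisons, each with a pair of values, a p-value and an adjusted p-value. Nothing in the tables names the columns, so this reading is an inference. The value columns were read as signal of single libraries, and no name ties a column to a digest. They were therefore used in no result reported here: 8 such columns, 4 per table, were left out. They had been looked at before this was decided, and the tests and settings added to those fixed beforehand were chosen after the tables were seen. As a consequence no level, direction or fold of modification, and no separation of 5mC from 5hmC, is analysed here. The p-values are the authors' own, taken from the deposited tables, and the test behind them is not given in the sources used here. The adjusted value of the second pair was set against the same thresholds as that of the first. It is read as a score and not as a probability, because the deposited column reaches 1.03. The deposited adjusted p-values equal the p-value times a number of tests over its rank, with 1397186 tests in haploid ESC and 1328393 in sperm, 2.21% and 2.39% above the rows used here. The aligner, counting and filters of the authors are not given in the sources used here, nor is the depth per library, so the precision it gives is unknown.

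The submitters' processing notes name the human build hg19. The tables name chromosomes 1 to 20, X and M, as in the macaque, so hg19 was not taken as their build. The last site on chromosome 1 is 229587268, while the last gene of the macaque reference table supplied here ends at 239870466. On chromosome 13 the last site lies 12342117 bp beyond the last gene of that table. No annotation of the tables' build was used, so positions are given as the tables give them and no gene is named. The planned promoter windows and gene lists (11 lists, the imprinted ones included) were not measured. The planned levels in percent and Fisher's exact tests were not run, since they need counts or levels of named digests. They were replaced by shares of calls and runs of calls.

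A call was a site with an adjusted p below 0.05. The numbers of sites listed and shared and the shares of calls per table cover all rows. The comparisons of chromosomes, of nuclear sites listed in one table alone, of calls at shared nuclear sites, of neighbours and of runs cover chromosomes 1 to 20 and X. They leave out mitochondrial sites (8 in haploid ESC and 11 in sperm) and 1 row per table for an unplaced sequence with the position -2. Sites were joined on chromosome and position, and a site of one table with no entry in the other is called missing there. Missing refers to the rows used here: since the implied numbers of tests exceed these rows by 30204 in haploid ESC and 31001 in sperm, a missing site can be one that was tested and is not used here. Shares have 95% Wilson intervals, which cover counting error only. Joint calls were set against independent lists. Runs were at least 5 shared sites at most 1000 bp apart, called in one table and not in the other. Runs of missing sites were at least 5 sites in a row among the sites of both tables, with no limit on distance. Run ends are the first and last site. The joint states of sites were shuffled 100 times within chromosomes with a fixed seed. For X against autosomes, autosomal sites were weighted to the X distribution in 20 classes of the distance to the nearest site, or in 20 by 20 classes of the haploid ESC p-values of both pairs. The rule fixed before the data were examined named the 10 longest candidate regions in each direction. It was applied to runs called in haploid ESC alone and in sperm alone, a definition of regions chosen after the tables were seen. Other runs, bins and sites named were chosen after their values were seen.

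The run search was tested on simulated data with the 1257412 real positions, independent calls at the real shares and 200 planted runs of 6 sites. It recovered 100% of runs in which each planted site was called in one cell type alone, which follows by construction, since such runs meet the rule of the search. With 90% and 80% of planted sites set to that state it recovered 75.5% and 56.5%. The other planted sites kept independent calls, some of which fall in that state too. Between 130 and 136 runs arose elsewhere, more than in the real tables, because independent calls leave more sites called in one table alone. Alternatives covered the threshold, the number and spacing of sites, shared sites alone, autosomes alone and calls matched by rank. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.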

Results

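CCGG sites were profiled in haploid embryonic stem cells (ESC) and in sperm of the rhesus macaque, Macaca mulatta. The series title names the haploid ESC as parthenogenetic, that is, derived from an egg without a paternal genome, and names imprinted differentially methylated regions as its subject. Imprinted regions carry DNA methylation on the maternal or the paternal allele alone. The assay, HMST-Seq, compares digests of genomic DNA. HpaII cuts unmodified CCGG sites, MspI also cuts methylated (5mC) and hydroxymethylated (5hmC) ones, and the label BGT marks an MspI digest paired with a glucosyltransferase, which protects 5hmC from MspI. Each cell type had 3 digests (HpaII, BGT_MspI and MspI) with 1 library each, so the 6 libraries held no replicates and no value below has a replicate error. The authors' deposited table of each cell type has no column names and was read as giving, per site, 2 pairwise comparisons of digests. Each comparison was read as holding a p-value and an adjusted p-value. The tables do not name the digests compared, so they are called here the first and the second pair. Comparisons of calls between the cell types assume that each pair joins the same digests in both tables, which nothing in them shows. The test behind the p-values is not given in the sources used here. A call is a site with an adjusted p below 0.05 and is read as a difference between the signals of 2 digests in these libraries. It says neither which signal was higher nor how modified the site was, and levels and directions of methylation are not analysed here. The read depth behind the calls is unknown.

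The first comparison asked which CCGG sites were listed in each cell type. The deposited tables are named for modified sites, so listing may itself depend on modification, which was not tested. The table of haploid ESC listed 1366982 sites and that of sperm 1297392, of which 1257420 were in both. Sperm lacked more of the other table's sites than haploid ESC did: 109561 nuclear sites (8.01% of the haploid ESC sites) were listed in haploid ESC alone and 39968 (3.08% of the sperm sites) in sperm alone. The X chromosome stood apart. In haploid ESC, 15.1% of X sites (95% Wilson interval 14.8% to 15.4%) had no entry in the sperm table, against 7.75% of autosomal sites (7.70% to 7.80%). Over the 20 autosomes this share ran from 7.21% on chromosome 14 to 8.40% on chromosome 16, so X lay above every autosome. In the other direction X was the lowest, with 2.10% of its sperm sites missing in haploid ESC against 3.11% on autosomes. Sperm carry X or Y, so lower depth of X is expected there, and it was not separated from other sources. The intervals cover counting error only, and neighbouring sites are not independent, so they are too narrow.

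Missing sites also came in runs. There were 14 runs of 5 or more neighbouring sites listed in sperm and all missing in haploid ESC. The shuffles gave 0.05 ± 0.22 such runs (SD over 100 shuffles of the sites within chromosomes) and at most 1 in a shuffle. The runs with the most sites lay side by side on chromosome 14. From 25321914 to 25331870, 12 sites in a row were missing in haploid ESC, and from 25333087 to 25338562 a further 10 were. Across the whole 16649 bp, 23 sites were listed in sperm and 1 in haploid ESC. Of 28 sites within 15 kb on either side, 22 were listed in haploid ESC and 24 in sperm. The 6 missing in haploid ESC were not spread evenly: 5 lay before the span, from 25314695 to 25318228, with a site listed in haploid ESC at 25317834 among them. A further listed site at 25320405 lay between them and the span. The thinning of sites thus began ahead of the span. Runs of 8 sites were missing in haploid ESC on chromosome X from 56176958 to 56188835 and on chromosome 1 from 218130701 to 218139863. A run of 6 was missing on chromosome 13 from 89722511 to 89726589. In the opposite direction, 19 runs were missing in sperm, 9 of them on X, against 5.98 ± 2.4 in the shuffles and at most 11. Shuffled runs on X were not counted by themselves. X had a higher share of missing sites than any autosome, so the 9 are not set apart from that share. The one with the most sites held 8, on chromosome 10 from 57117124 to 57122306. For both classes the one-sided permutation p was 0.0099, the smallest that 100 shuffles can give. It tests clustering along the chromosome in these tables, not the cell types against replicate error. These runs were singled out after the tables were seen.

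**Figure D1:**
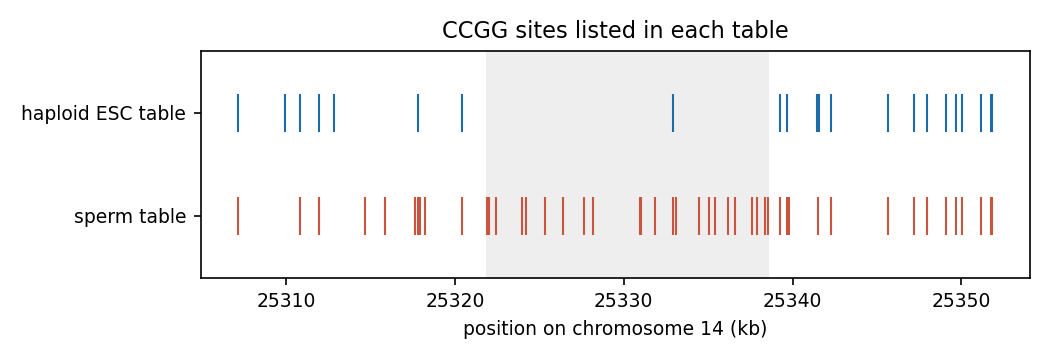
CCGG sites listed in the haploid ESC table (blue, upper row) and in the sperm table (red, lower row) on chromosome 14, with position in kb on the horizontal axis and 1 tick per site. The shaded 16649 bp hold 23 sites of the sperm table and 1 of the haploid ESC table.

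The second comparison asked how many sites were called within each cell type. Calls for the first pair covered most of the listed sites in both cell types, and calls for the second pair were few. For the first pair the authors' deposited tables called 913715 haploid ESC sites (66.8%) and 901631 sperm sites (69.5%). For the second pair the authors' deposited tables called 152343 sites (11.1%) in haploid ESC and 100153 (7.72%) in sperm. Strict calls shifted the balance of the second pair: at an adjusted p below 0.001 the authors' deposited tables held 1.33% of haploid ESC sites and 1.54% of sperm sites. With 1 library per digest, none of these differences between the cell types was tested, and depth alone can move a share of calls.

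Chromosomes differed more in sperm than in haploid ESC. In the authors' deposited table of haploid ESC, the share of first-pair calls per autosome ran from 65.6% on chromosome 18 to 69.6% on chromosome 19. In the authors' deposited table of sperm it ran from 66.5% on chromosome 16 to 73.8% on chromosome 5. The X chromosome was called at 67.2% of haploid ESC sites (95% Wilson interval 66.8% to 67.6%) in the authors' deposited table, close to the autosomal 66.8%. In sperm the authors' deposited table called 63.5% of X sites (63.0% to 64.0%) and 69.7% of autosomal sites, a ratio of 0.91, and X lay below every autosome. For the second pair the authors' deposited table of sperm called 3.58% of X sites (3.41% to 3.76%) against 7.86% of autosomal sites, a ratio of 0.46, while in haploid ESC the authors' deposited table called 11.4% and 11.1%, a ratio of 1.02. Lower depth of X in sperm, which carry X or Y, was not separated from a difference of modification.

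**Figure D2:**
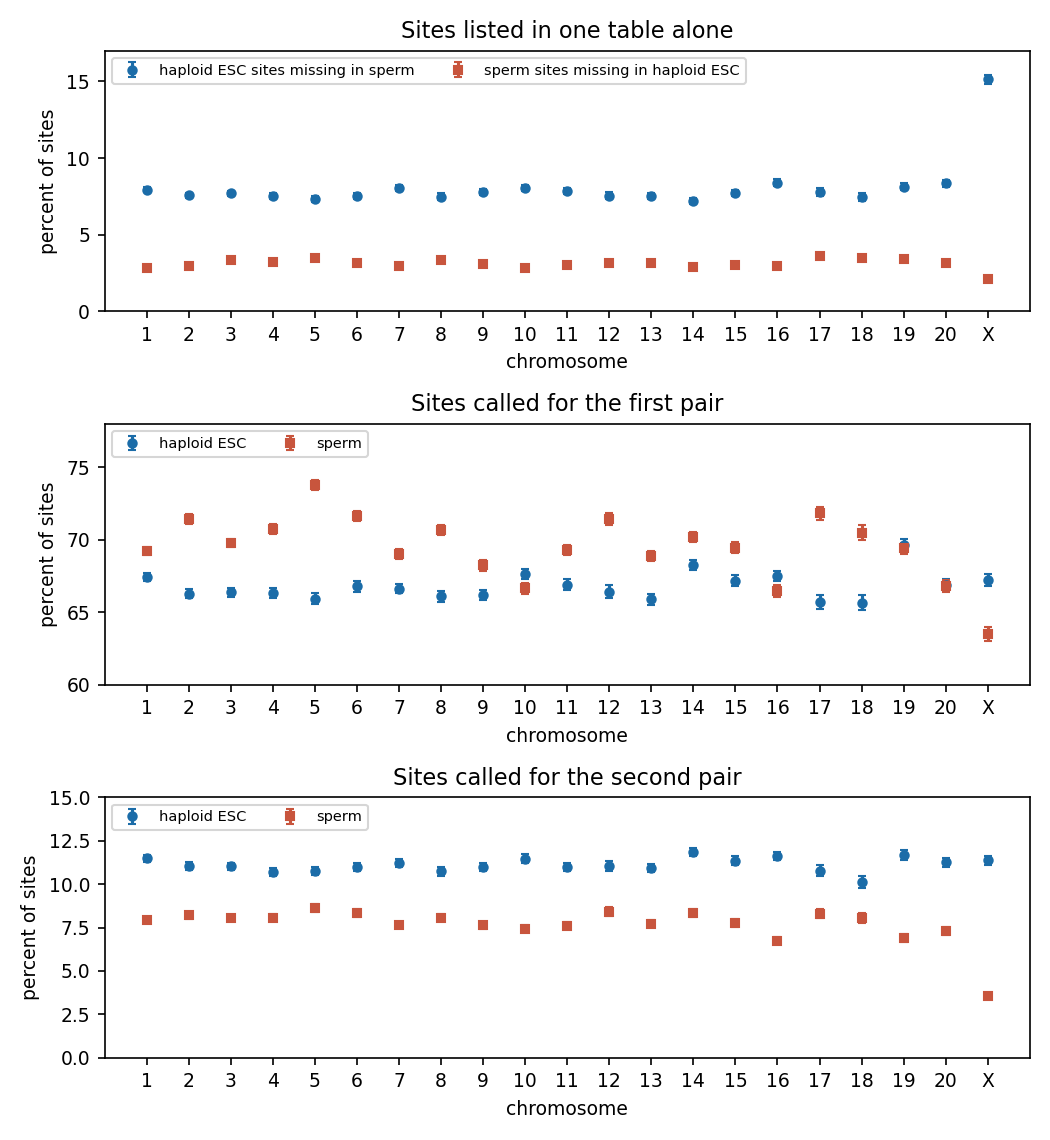
Per chromosome (horizontal axis), the percent of sites listed in 1 table alone (upper panel, axis from 0), called for the first pair (middle panel, axis from 60 to 78) and called for the second pair (lower panel, axis from 0), for haploid ESC (blue circles) and sperm (red squares), with 95% Wilson intervals. On X, 15.1% of haploid ESC sites were missing in sperm, and in the authors' deposited table of sperm 3.58% of X sites were called for the second pair.

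Neighbouring sites tended to share their call for the first pair, and the tendency reached further in sperm. The phi coefficient, the correlation of yes-or-no calls across sites, was 0.12 in haploid ESC and 0.14 in sperm for sites 50 to 100 bp apart in the authors' deposited tables. At 200 to 500 bp it was 0.07 and 0.12 in the authors' deposited tables, and at 500 to 1000 bp 0.04 and 0.08. For the second pair no phi exceeded 0.06 in any distance class of the authors' deposited tables, but the small share of second-pair calls limits phi, so the pairs are not compared by it. Sites within a table are not independent replicates, and the difference between the cell types was not tested.

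**Figure D3:**
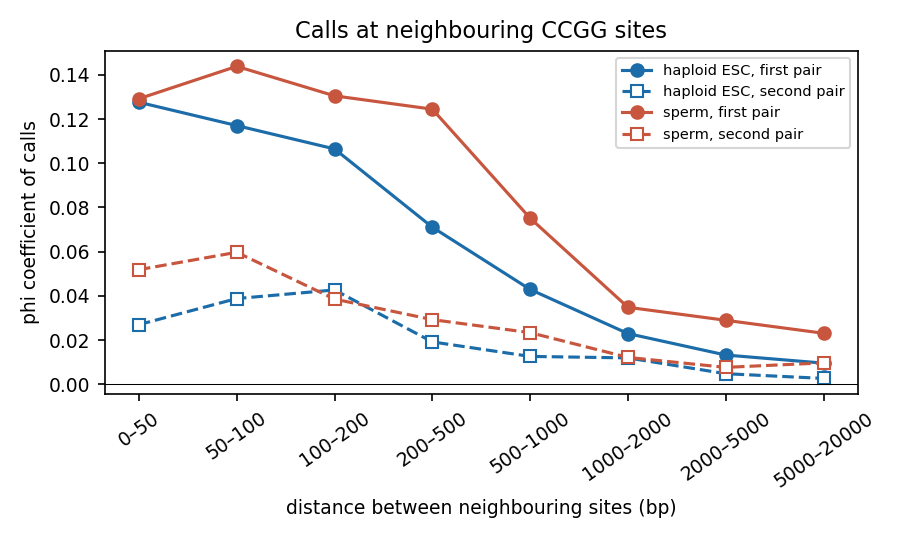
Phi coefficient of calls at neighbouring CCGG sites (vertical axis) against their distance in bp (horizontal axis, in classes), for haploid ESC (blue) and sperm (red), first pair (filled circles) and second pair (open squares), from the authors' deposited tables. At 200 to 500 bp the first pair had 0.12 in sperm and 0.07 in haploid ESC.

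The third comparison set the calls of haploid ESC beside those of sperm, site by site, over 1257412 shared nuclear sites. It rests on the assumption that each pair compares the same digests in both cell types. For the first pair, most sites called in one cell type were also called in the other, and for the second pair most were not. The authors' deposited tables called 641292 sites (51.0%) for the first pair in both cell types, 209595 (16.7%) in haploid ESC alone, 236995 (18.8%) in sperm alone and 169530 (13.5%) in neither. Joint calls were 1.08 times the 594334 expected of independent lists. At an adjusted p below 0.001 the authors' deposited tables gave 341228 joint calls, 1.32 times the number expected. The second pair had 19860 joint calls in the authors' deposited tables, 1.74 times the 11399 expected. Its calls in one cell type alone in the authors' deposited tables numbered 125480 (9.98%) in haploid ESC and 78756 (6.26%) in sperm. Across the cell types phi was 0.17 for the first pair and 0.078 for the second in the authors' deposited tables. The ratio to the expected number and phi both depend on the share of calls, so the pairs are not ranked by either. The first-pair p-values of the authors' deposited tables ranked alike across shared sites with Spearman's rho = 0.36, and those of the second pair with rho = 0.24. A site called in one cell type alone is not thereby shown to differ between them.

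Runs of neighbouring sites called in one cell type alone were few. A run was at least 5 shared sites at most 1000 bp apart, all called for the first pair in one cell type and none in the other. In the authors' deposited tables, haploid ESC alone had 44 such runs and sperm alone 45. Shuffling the joint calls within chromosomes 100 times gave 19.8 ± 4.1 (SD over shuffles) and 30.4 ± 5.9. No shuffle reached 44 for haploid ESC (one-sided permutation p = 0.0099), and the highest for sperm was 47 (p = 0.050). Runs called in both cell types were far more frequent: the authors' deposited tables held 8798 of them, against 3405 ± 60 in the shuffles. Runs called in neither exceeded the shuffles too, with 17 in the authors' deposited tables against 6.89 ± 2.7. The shuffles remove any likeness of neighbouring sites, so these p-values test clustering along the chromosome and not a difference between the cell types. Both counts of runs called in one cell type alone depend on the threshold. At an adjusted p below 0.001 the authors' deposited tables gave 110 runs in haploid ESC alone and 224 in sperm alone.

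The longest run called in haploid ESC alone lay on chromosome 10 from 81682822 to 81686292 and held 6 sites. Its sperm sites had adjusted p-values from 0.055 to 0.25 in the authors' deposited table, and its haploid ESC sites reached 0.042, close to the threshold. A run on chromosome 13 from 125855593 to 125857916 had 5 sites, each with an adjusted p of 0.00071 or less in haploid ESC and of 0.055 or more in sperm in the authors' deposited tables. On chromosome 16, 5 sites from 13074641 to 13076926 reached at most 0.0016 in haploid ESC and at least 0.067 in sperm in the authors' deposited tables. Chromosome 16 held another of the 10 longest, from 57258946 to 57261491 with 5 sites. Its lowest adjusted p in sperm, 0.12 in the authors' deposited table, was the farthest from the threshold among the 10. Its highest adjusted p in haploid ESC was 0.042 in the authors' deposited table, close to the threshold. The others lay on chromosome 12 from 102832167 to 102834696 and from 96199744 to 96202101, chromosome 1 from 24167887 to 24170368, chromosome 20 from 73231431 to 73233847, chromosome 7 from 138067244 to 138069647 and chromosome 13 from 21456848 to 21459169, with 5 or 6 sites each.

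The longest run called in sperm alone lay on chromosome 5 from 182425953 to 182428408, with 5 sites. Another of the 10 lay on chromosome 4 from 162737031 to 162739385. Its 5 sites had adjusted p-values of 3.9e-08 or less in sperm and between 0.13 and 0.34 in haploid ESC in the authors' deposited tables. On chromosome 12, 5 sites from 4125294 to 4127439 reached at most 1.8e-15 in sperm and at least 0.087 in haploid ESC in the authors' deposited tables. On chromosome 5, 5 sites from 93835721 to 93838014 reached at most 5.8e-14 in sperm and at least 0.051 in haploid ESC in the authors' deposited tables. The remaining runs lay on chromosome 1 from 197220860 to 197223142 and from 214049741 to 214051915, chromosome 14 from 2915200 to 2917385, chromosome 12 from 102426333 to 102428226, chromosome 7 from 156981036 to 156982852 and chromosome 9 from 1575143 to 1576895, each with 5 sites. The stretch with the most sites called in both cell types held 27 sites over 6767 bp on chromosome 16 from 25581528 to 25588294. Genes at these positions are not reported here, since no annotation of the tables' genome build was used.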

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

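The tests of X depth and of chance runs were chosen after the results they measure were seen. Flags came from values that point in opposite directions in the cell types or that lie outside the main comparisons.

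The share of first-pair calls on X was below that of autosomes in sperm, by -6.20 percentage points in the authors' deposited table, and above it in haploid ESC, by 0.41 points in the authors' deposited table, an excess within its counting interval. Over shared sites alone the values were -6.33 and 0.79 points in the authors' deposited tables, so the size of the excess depends on the sites used. With 1 library per digest the difference between the cell types was not tested. The X chromosome also had the highest share of sites missing in sperm. The spacing of sites on X, measured as the distance to the nearest site, is argued against as the source. X exceeded autosomes in the percent missing by 7.30 points with autosomal sites weighted on that distance, against 7.38 unweighted. Weak evidence at X sites in haploid ESC is argued against too, with 7.53 points after weighting on the haploid ESC p-values. Sperm carry X or Y and haploid ESC an X, so lower depth of X is expected in sperm. Whether it accounts for these differences stays open. The X to autosome ratio of strict first-pair calls was 0.89 in sperm, between the bounds of 0.8 and 0.9 set for it, and 1.01 in haploid ESC. That of strict second-pair calls, for which no bound was set, was 0.37 and 0.92. A difference of X modification between the cell types stays open as well and was not tested.

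Joint first-pair calls of the authors' deposited tables exceeded independent lists 1.08-fold. The distance of a site to its nearest neighbour is argued against as the source. Within classes of that distance the ratio was still 1.08, which keeps 95.4% of the excess. Density of CCGG sites over wider stretches was not measured and stays open. Depth that is alike at a site in both cell types, and modification that is alike in both, stay open and were not tested.

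The runs of sites missing in haploid ESC, led by 16649 bp on chromosome 14, are the other pattern to follow up. Chance runs of single missing sites are argued against, since 0 of 100 shuffles gave as many as 14. Repeat copies at recurring distances cannot be told apart from other sources, because their share of neighbouring pairs within the runs was 1.30 times that of all pairs and rests on 3 of 75 pairs. A deletion in the haploid ESC line and a difference between the animals' genomes are possible explanations that were not tested. So are a filter of the authors and rows that are not used here. The deposited tables are named for modified sites, so a lack of modification at the missing sites was not told apart from these.

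Mitochondrial sites count in the totals per table and entered no comparison of chromosomes, shared sites or runs. The authors' deposited table of haploid ESC called 7 of 8 of them for the first pair, and that of sperm 10 of 11.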

How the results depend on the processing

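The thresholds of 0.01 and 0.001, the p-value rule for sites not called, calls matched by rank, both weightings and runs of 4 missing sites were added after the data were seen. In all, 12 of 46 alternative values stayed within the interval or the 1.5-fold range set for them. All calls are those of the authors' deposited tables. Runs called in haploid ESC alone and in sperm alone numbered 2436 and 2264 with at least 3 sites, 0 and 0 with at least 10, 8 and 14 with neighbours at most 500 bp apart, 87 and 123 at 0.01, 110 and 224 at 0.001, and 16 and 21 where sites not called had p of 0.05 or more. With equal numbers of sites called by rank, 67 runs were in haploid ESC alone and 36 in sperm alone, so which class is the larger depends on the setting. Fewer runs pass by construction with more sites, with shorter distances and with the p-value rule for sites not called. The cause of the other shifts was not tested. First-pair calls covered 53.0% of haploid ESC and 57.6% of sperm sites at 0.01, 41.5% and 48.1% at 0.001, 67.7% and 69.8% over shared sites, and 69.7% of sperm sites on autosomes. Second-pair calls covered 3.93% and 3.35% at 0.01, 1.33% and 1.54% at 0.001, 11.6% and 7.84% over shared sites, and 7.86% of sperm sites on autosomes. Joint calls were 1.18 and 1.32 times the number expected at 0.01 and 0.001 for the first pair, and 2.68 and 4.42 times for the second. This ratio can rise merely because calls become rarer. Phi across the cell types was 0.23 and 0.27 for the first pair at these thresholds, and 0.065 and 0.051 for the second. The X minus autosome share of first-pair calls in sperm was -5.47 points at 0.001. With at least 4 sites, 158 runs were missing in sperm, against 61.2 on average in the shuffles, and 39 in haploid ESC, against 0.82. No paired analysis was possible because each digest of each cell type has 1 library, and for the same reason no replicate could be left out. Coverage minimums, scaling, summed tags, 5hmC differences, thresholds in percentage points, promoter windows and imprinted lists were not run, since they need values of named digests or gene positions. The unknown depth limits each share of calls.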

Other observations

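The values in this part were chosen after the tables were seen. Some distances between neighbouring sites recurred far more often than nearby distances, and haploid ESC sites at these distances were called less often. Between 40 and 400 bp, 13 distances occurred at least 2 times as often as nearby ones. The most frequent was 234 bp, with 5184 pairs against a median of 947.5 at nearby distances, followed by 202 bp with 5108. Shared sites in pairs 234 bp apart were called for the first pair at 65.4% in haploid ESC, against 70.7% at nearby distances, in the authors' deposited table. In sperm they were called at 75.6% against 73.7% in the authors' deposited table. At pairs 68 bp apart the authors' deposited tables called 63.7% in haploid ESC and 71.6% in sperm, against 73.4% and 74.7% nearby. The haploid ESC share lay below the nearby share at all 13 distances, and the sperm share lay above it at 4 of the 13. Many of the 13 are adjacent values, such as 201 to 205 bp and 233 to 235 bp, so they are not separate observations. The sequences at these pairs were not examined.

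Stretches of 100 kb differed in how often their sites were called. Among 24022 bins with at least 20 shared sites, 445 had a share of first-pair calls at least 30 points higher in sperm in the authors' deposited tables, against 147.8 on average and at most 165 in 20 shuffles of the joint calls within chromosomes. In the other direction 17 bins did, against 44.3 in the shuffles. The shuffles remove any likeness of neighbouring sites and keep the overall balance of calls of each chromosome. The widest gap in the authors' deposited tables lay on chromosome 5 from 30300001 to 30400000, where 34.5% of 29 sites were called in haploid ESC and 89.7% in sperm. A bin on chromosome 6 from 162600001 to 162700000 had 37.5% and 90.6% of 32 sites called in the authors' deposited tables. On X from 36600001 to 36700000 the authors' deposited tables called 91.3% of 23 sites in haploid ESC and 43.5% in sperm, the widest gap in that direction. Of the 10 bins with the widest gaps in that direction, 6 lay on X, where the authors' deposited table of sperm called fewer sites over the whole chromosome (63.5%, against 69.7% on autosomes), so the X bins are not set apart from that.

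Sites listed in one table alone were called less often there. The authors' deposited table of haploid ESC called 57.3% of the sites listed there alone for the first pair, against 67.7% of shared sites. The authors' deposited table of sperm called 58.4% of the sites listed there alone, against 69.8%.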
